A study of Cricetulus griseus and Cricetulus griseus
Mus musculus and Mus musculus with 202 samples.

How the data were processed

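RNA was compared on 202 2-colour arrays. Of these, 198 arrays set RNA from a T31 radiation hybrid line against RNA from A23, the hamster cell line that received the donor DNA. There were 99 such lines, numbered up to 100 with 67 absent, and 2 arrays per line. A radiation hybrid line carries random fragments of the donor genome, here mouse, in a recipient cell, here hamster. The other 4 arrays set mouse RNA against hamster RNA, with 2 arrays for brain and 2 for liver. All columns could be assigned to a group from their labels. Per the labels' protocols, cells were grown in DMEM with serum, RNA was extracted with a column kit and total RNA was labelled directly. Scanner software, background correction and normalisation are not given in the sources used here.

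The deposited values are log10 ratios of Cy5 over Cy3, per the labels. Per the labels, replica 2 of each line and tissue exchanged the dyes of replica 1, so the replicate number is also the dye orientation. The deposited log10 ratios were multiplied by the sign of the orientation and converted to log2, which gave hybrid over A23 for the lines and mouse over hamster for the tissues. The table held 20868 features and 0 missing values. The lowest log10 value was -2, which acts as a floor, and the highest was 3.37. A median of 8.23% of an array's values were exactly 0, from 0 to 33.6%. Array medians lay between -0.0110 and 0.0118 on the log10 scale, and the spread of an array (SD, log2) ran from 0.397 to 2.43 with a median of 0.838. The deposited ratios carry no intensities, so the number of arrays limits the precision and signal over background is unknown.

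The values of the 4 tissue arrays showed a further step. In 20720 of the 20868 features (99.3%) the 4 linear Cy5 over Cy3 ratios had a median of 1, within a tolerance of 1e-06, and each of the other 148 features held a value at the floor. Each feature had thus been centred over these 4 arrays before the floor was applied. No such centring was present in the hybrid arrays, where 0% of the features without exact zeros had a median of 1. Because the dyes were exchanged, the offset left by centring cancels in each tissue's mean and in the difference of tissues, but it widens the spread between the arrays of a tissue. A tissue mean that rests on a value at the floor is a bound, and is given as one.

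Gene symbols came from the probe table supplied for the array. A single symbol was given for 17786 features, several symbols for 16, and 3066 features had no gene there. Features with 1 symbol were averaged per gene, which gave 16504 genes, 1152 of them with several features. Genes had to be measured on at least 80% of the arrays of a comparison, a filter that removed none. For matching to the gene lists, 10 symbols were renamed by hand. Gene positions were not analysed here, so neighbourhood on a chromosome was tested through 4 lists of genes that lie together.

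The panel mean was tested with limma 3.58.1 in R 4.3.3 on 1 value per line, the mean of both of its arrays, against 0. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute mean of at least 0.2 on the log2 scale. A23 was on every array and never against itself, so its own spread between cultures does not enter the test. Differences between lines were tested with limma's moderated F test on the 198 arrays, with line and dye orientation as terms. The same fit gave the calls of each line against A23. The 4 tissue arrays were fitted together with tissue as the factor, which left 2 residual degrees of freedom, and brain, liver and brain minus liver were tested. Tk1 and its listed neighbours were compared with 100000 random gene lists of the same size, and shares were compared with Fisher's exact test. Correlation across lines within a position list was compared with 1000 random lists. The labels call the 2 arrays of a line or tissue biological replicas, the second with dyes exchanged, and name no animals or cultures. The p-values throughout measure only the spread between these samples, which may be technical. For tissues and for calls of single lines that is the spread between 2 arrays, which includes any effect of array and dye left by the fit.

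In all, 34 gene lists were tested for the panel mean and the 3 tissue comparisons: position lists, lists of processes and markers relevant to cultures, and lists for brain and liver. Members were counted with adjustment over all genes and over the list alone. Lists were tested with limma's camera with a preset correlation of 0.01 and with an estimated correlation, and adjusted over the lists of a comparison. In the tissues the estimated version rests on 2 residual degrees of freedom, and on 1 with the replicate block. It could hardly pass there, so whether correlation between genes accounts for a tissue list's call stays open. The histone list was matched in only 7 of its 30 genes and is not discussed. The genes named were set by rule. They were Tk1 and the 12 highest and 12 lowest panel means among called genes with the same sign in at least 80% of lines, the 12 genes with the largest F between lines, the 10 highest and 10 lowest called genes of each tissue with the same sign on both arrays, the 8 highest and 8 lowest of the difference of tissues, and up to 4 members with the smallest p from each list discussed. The design, the lists, the naming rule and most alternatives were fixed before the data were examined, and later additions are identified where they appear.

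Steps were tested on simulated data made from the spread of the real arrays, over 16504 genes. For the panel mean, 84% of 50 genes changed by 0.3 on the log2 scale were recovered, 94% at 0.5 and 100% at 1 and at 2, and 0.0797% of unchanged genes were called. For differences between lines, 47.8%, 94.0% and 100% were recovered at an SD over lines of 0.5, 1 and 2. For mouse against hamster brain, 0% were recovered at 1, 38% at 2, 68% at 4 and 78% at 6. For brain minus liver the shares were 0%, 16%, 44% and 66%. The simulated tissue arrays held independent normal noise with each gene's residual spread, and changes in brain only. The offset left by centring entered them only as a wider independent spread, and the floor was not applied. The tissue shares are thus only a rough guide to the real arrays.

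The match of a line's arrays was checked by ranking, for each line, its second array among all 99 second arrays by correlation with the first. The check of the tissue arrays' replicate numbers compared the deviations of the arrays from their tissue means. Replicate 1 minus replicate 2 of brain and of liver correlated at r = 0.439 across 16504 genes, which are not independent replicates, and the centring sets part of that value. The pairing comes from the labels, since the number marks the dye orientation. Alternatives changed the centring of arrays and their scaling (to a common median absolute value in limma, in place of the planned scaling, which gave no usable values on log ratios), the treatment of exact zeros, features in place of genes, the replicates, the dye term as a replicate block, the lines and arrays included, the size limit and the estimate of spread. The filters on missing values were not run, since no value was missing. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The random seed was 1.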

Results

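Gene expression was measured in 99 mouse-hamster hybrid lines of the T31 panel, each against the hamster recipient line A23 on 2 arrays with exchanged dyes. Mouse brain was also compared with hamster brain, and mouse liver with hamster liver, on 2 arrays per tissue with exchanged dyes. Each array gave 20868 ratios, which covered 16504 genes. Arrays of the same dye orientation correlated weakly across genes, with a median r of 0.225 for replicate 1 and 0.233 for replicate 2. Genes are not independent replicates. When each line's second array was ranked by correlation with its first, 28 of 99 lines ranked their own second array first, against 1 by chance.

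The first comparison asked which genes the hybrids as a panel express above or below the recipient. Tk1, the thymidine kinase that salvages thymidine for DNA synthesis, stood above A23 in nearly every line. A23 lacks this activity and T31 lines were selected for the donor gene, so Tk1 checks the direction of the ratio. The highest genes beside it included Pigr, the receptor that carries IgA across epithelia, Slc38a10, an amino acid transporter, and Hook1, which links cargo to microtubules. The lowest included Lum and Col3a1, which build and organise collagen fibrils, the metallothionein Mt1, and Txnip, an inhibitor of thioredoxin.

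Tk1 averaged 1.84 ± 0.08 on the log2 scale (SE, n = 99), 3.58-fold above A23, and was above 0 in 98 of 99 lines (limma, adjusted p = 2.2e-38). Its mean was 1.52 in replicate 1 and 2.16 in replicate 2. Pigr averaged 3.59 ± 0.14, Slc38a10 3.49 ± 0.11, Tsga10 3.19 ± 0.14, Hook1 3.18 ± 0.14 and Cst9 2.64 ± 0.11, each above 0 in 99 of 99 lines. Anapc11, a subunit of the anaphase-promoting complex, averaged 2.36 ± 0.18 and was above 0 in 88 lines. Means of 4930402H24Rik, Trim47, 1700067P10Rik, Kcnj12 and Olfr608 lay between 2.01 and 2.32. Lum averaged -3.27 ± 0.11 and was above 0 in 1 line, Col3a1 averaged -2.46 ± 0.15, Col2a1 -2.17 ± 0.15, Mt1 -1.52 ± 0.11 and Txnip -1.34 ± 0.10. Ccl20 averaged -2.06, Enpep -1.47, Ndrg1 -1.28, Celf2 -1.23, Spats2l -1.20, Snrpn -1.15 and Snrpb -1.12. The size of several of the lowest means depended on the dye orientation: Lum averaged -4.86 in replicate 1 and -1.68 in replicate 2, and Col3a1 -4.19 and -0.73. Ccl20, Celf2 and Snrpb passed the test in only 1 of the orientations.

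**Figure D1:**
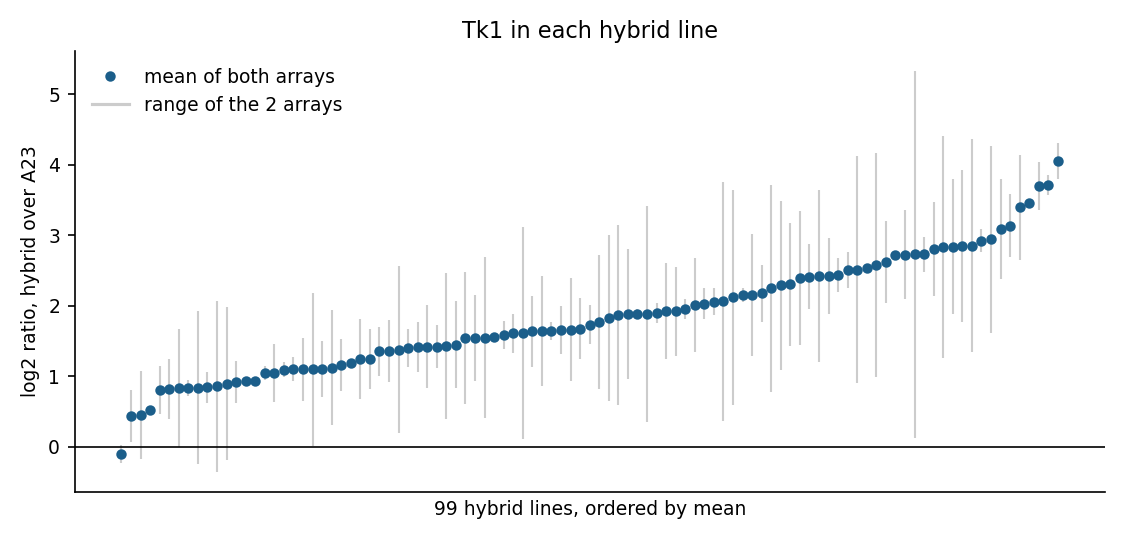
Log2 ratio of Tk1, hybrid over A23, for each of the 99 lines in order of its mean; points are means of both arrays and bars run from one array to the other. The mean lies above 0 in 98 lines.

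In total 3224 genes were higher and 1887 lower in the hybrids. Without the size limit of 0.2 the counts were 5033 and 4462. Only 1235 of the higher and 745 of the lower genes also passed in each dye orientation alone, and 1806 of the 5111 called genes had opposite signs in the orientations. Across genes, the means of the orientations correlated at r = -0.226. In the 28 lines that ranked their own second array first (the matched lines), 2558 genes were higher and 933 lower. The matched-line fit left out 71 lines, so a call lost there can come from fewer lines or from a smaller mean.

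The genes near Tk1 were asked about next, since donor DNA around a selected gene tends to be kept with it. Several listed neighbours rose along with Tk1. They included Trim47, a ubiquitin ligase, Lgals3bp, a secreted glycoprotein that binds galectins, and Prpsap1, which binds the enzyme that makes phosphoribosyl pyrophosphate. Most of the list moved little.

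The 77 measured neighbours had a median of 0.16 on the log2 scale, against a median of 0.01 for random lists with a 95% range of -0.04 to 0.07. The permutation p was 1e-05, the smallest that 100000 draws can give (two-sided). Trim47 averaged 2.14 ± 0.11 and Lgals3bp 1.21 ± 0.06, and Prpsap1 was 2.83-fold above A23. Of the 77 neighbours, 32 were higher (41.6%, against 19.4% of other genes; odds ratio 2.95, 95% interval 1.81 to 4.75, Fisher's exact p = 8.4e-06). In both orientations alone 19 were higher (24.7% against 7.40%, odds ratio 4.10, interval 2.30 to 7.01, Fisher's exact p = 2.7e-06). Random lists and Fisher's test treat the neighbours as independent. The Tk1 list varied together across lines (mean correlation 0.0523, against 0.0125 for random lists), so these p-values are too small and the intervals too narrow. The 4 lower neighbours, named after their values were seen, were Jmjd6 at -0.68, Rbfox3 at -0.44, Cbx2 at -0.22 and Mafg at -0.22. The median was 0.16 in replicate 1, which did not pass (permutation p = 0.0723), and 0.15 in replicate 2 (p = 1e-05). With Tk1 itself, 33 members were higher and 4 lower, the same numbers when adjusted over the list alone, and the list was higher by camera (adjusted p = 3.3e-07; adjusted p = 0.0325 with an estimated correlation).

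**Figure D2:**
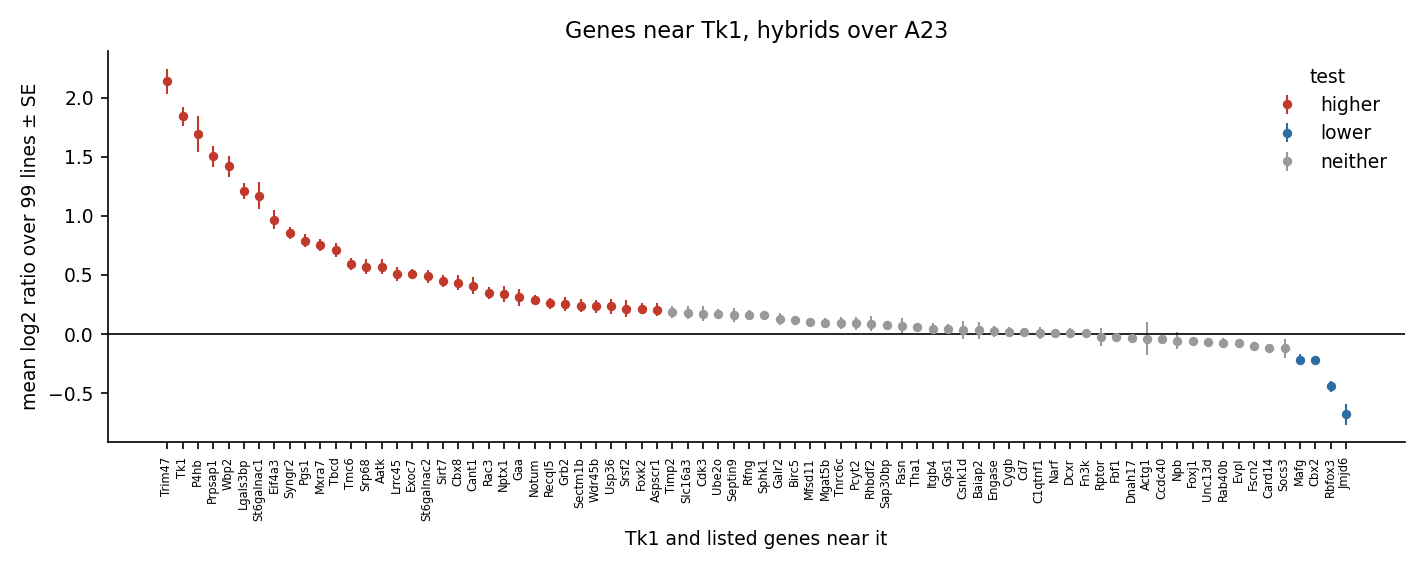
Mean log2 ratio, hybrids over A23, of Tk1 and its 77 measured listed neighbours, with SE over 99 lines; colours give the outcome of the test. Of the neighbours 32 were higher and 4 lower.

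Among listed genes of cell processes, higher ones included Cdt1, which licenses origins, Pole2, a subunit of a replicative polymerase, and Mcm5 of the replicative helicase. Top2a and Racgap1, which act in chromosome separation and cytokinesis, were also higher. The ribosomal protein gene Rps14 and the chaperone gene Hspa8 were lower.

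Of 37 measured DNA replication genes, 23 were higher and 1 lower, the same numbers when adjusted over the list alone (camera adjusted p = 7.0e-06; adjusted p = 0.237 with an estimated correlation). Cdt1 averaged 1.12 ± 0.07, Pole2 1.06 ± 0.07, Mcm5 0.98 ± 0.07 and E2f1 0.82 ± 0.07, and the lower gene, named after its value was seen, was Orc2 at -0.34. The list's median was 0.27 in replicate 1 and 0.17 in replicate 2. Of 31 mitosis genes, 15 were higher and 0 lower by limma, also when adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. The list was higher by camera (adjusted p = 1.6e-04; adjusted p = 0.506 with an estimated correlation). Top2a averaged 0.97 ± 0.09, Racgap1 0.68 ± 0.08 and Anln 0.39 ± 0.04, although 1 of Anln's features alone gave 0.03 and no call. Bub1 averaged 0.82 ± 0.08 but was -0.064 in replicate 1 and 1.71 in replicate 2. Among 31 ribosomal protein genes, 3 were higher and 12 lower, the same when adjusted over the list alone (camera adjusted p = 0.0173; adjusted p = 0.748 with an estimated correlation). Their median was -0.51 in replicate 1 and 0.15 in replicate 2, so the direction depended on the orientation, and in the 28 matched lines 2 were lower. Rps14 averaged -0.77 ± 0.12, Rps19 -0.75 ± 0.12, Rpl7 -0.65 ± 0.10 and Rps15 -0.62 ± 0.09, and the first 3 of these lost their call in the matched lines.

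Among 18 chaperone genes, 3 were higher and 10 lower, the same when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0747). Hspa8 averaged -0.68 ± 0.12, Cct3 -0.67 ± 0.11 and Tcp1 -0.57 ± 0.10, none of which was called in the 28 matched lines, while Hspb8 averaged 0.47 ± 0.07. Of 37 matrix genes, 18 were higher and 6 lower, the same when adjusted over the list alone (camera adjusted p = 0.996), and the list's median of 0.19 differed in sign from its mean of -0.04. Sparc averaged 0.71 ± 0.10 but was -0.71 in replicate 1 and 2.12 in replicate 2. Of 19 cholesterol synthesis genes, 3 were higher and 7 lower, the same when adjusted over the list alone (camera adjusted p = 0.539). Sqle averaged -0.87 ± 0.11 and Hmgcs1 -0.80 ± 0.12, yet in replicate 2 they were 0.39 and 0.85, and neither was called in the 28 matched lines. Nsdhl averaged -0.48 and Srebf2 -0.37, and the matched lines called neither. Of the 34 lists, 4 passed camera in the panel: Tk1 and its neighbours, DNA replication, mitosis and ribosomal proteins. Only the Tk1 list kept its call (adjusted p = 0.0325 with an estimated correlation), and the other 3 did not (0.237, 0.506 and 0.748).

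The second comparison asked which genes differ between the lines, since each holds other mouse fragments. Rpl39, a ribosomal protein gene, Xist, the RNA that silences an X chromosome, Atp5a1 of the mitochondrial ATP synthase and the interferon-induced Ifitm3 stayed near the level of A23 in many lines and rose far above it in others. S100a11, a calcium-binding protein, also differed, but many of its ratios are exactly zero.

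By the moderated F test in limma, 1466 genes (8.88%) differed between lines. The intraclass correlation of a line's arrays had a median of 0.0414 over all genes and 0.367 over the called ones. Rpl39 had the largest F, with an intraclass correlation of 0.883 (adjusted p = 1.2e-30), and 10 of 99 lines above a log2 ratio of 1. Xist had 0.808 and 7 such lines, Atp6v0e 0.817 and 16, Atp5a1 0.794 and 23, Ifitm3 0.781 and 28, and Nme2 0.781 and 22. Ndufs5 had 0.773 and 13, Dtymk 0.767 and 28, Serpinb9d 0.764 and 19, Sod2 0.760 and 20, S100a11 0.759 and 46, and C1ra 0.752 and 27. Ratios were exactly 0 on 62.1% of arrays for C1ra, 38.9% for S100a11 and 29.8% for Dtymk, so these 3 could not be tested with exact zeros as missing. The highest line reached 7.12 for Rpl39, 5.81 for Xist and 7.17 for Ifitm3. In replicate 1 the floor caps the ratio of hybrid over A23, so such high values may be bounds. Without the dye term 767 genes were called. In the 28 matched lines 3573 were, but these lines were chosen because their arrays correlate, which by itself favours calls. A single line had a median of 105 genes higher and 12 lower than A23, and counts ran from 0 to 3238 higher and from 0 to 3888 lower. Both highest counts came from line 42, whose first array had the widest spread of all arrays (SD 2.43).

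**Figure D3:**
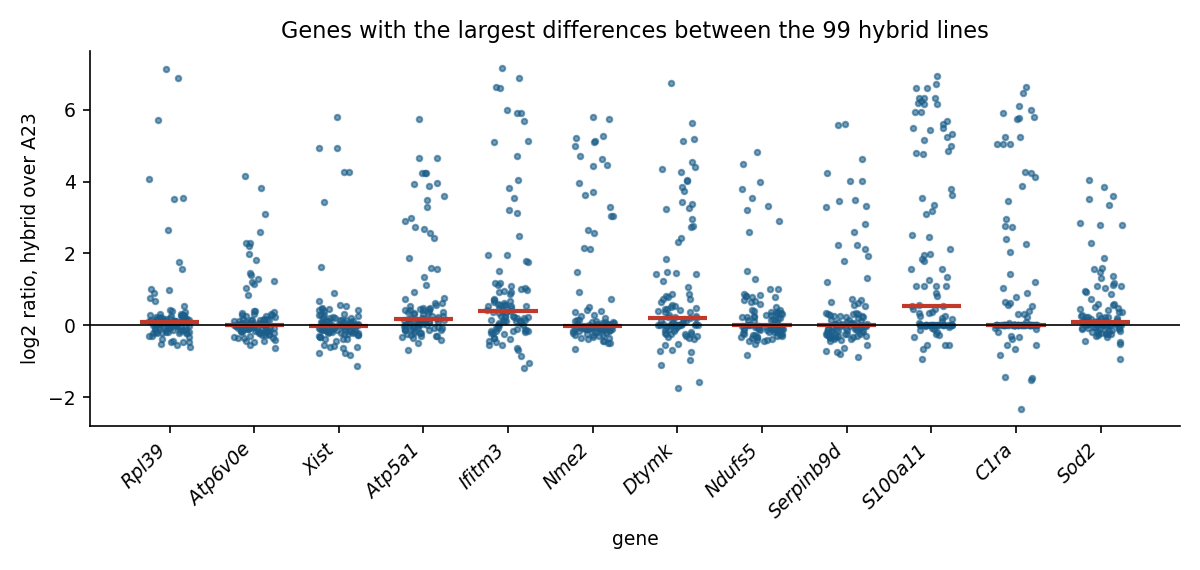
Log2 ratio, hybrid over A23, in each of the 99 lines for the 12 genes with the largest F; red bars are medians over lines. Rpl39 exceeded 1 in 10 lines and S100a11 in 46.

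Genes that lie together on a mouse chromosome were asked whether they vary together between lines. The lists covered the surroundings of Tk1, the class III region of the major histocompatibility complex, a stretch of the X chromosome from Flna to Bgn, and the imprinted region at the end of chromosome 7. Members of each list varied together more than random genes.

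Mean Pearson correlation across the 99 lines was 0.0523 for the Tk1 list, 0.114 for the class III region, 0.127 for the X chromosome stretch and 0.050 for distal chromosome 7. Random lists averaged 0.0125, 0.0125, 0.0115 and 0.0127. One-sided permutation p, adjusted over the 4 lists, was 0.00133 for the first 3, from a raw p of 0.001, the smallest that 1000 draws can give, and 0.0190 for distal chromosome 7. The mean Spearman correlations were 0.0492, 0.105, 0.0999 and 0.0406. With the first 5 components removed from the line means, the Pearson values were 0.0533, 0.0370, 0.0912 and 0.0549. The class III value fell to 0.0648 in replicate 2 alone and still passed. From replicate 2 alone the distal chromosome 7 list gave 0.0284 and did not pass (adjusted p = 0.0589, the highest of a range from 0.00133 over its alternatives).

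The third comparison set mouse brain against hamster brain, which shows where sequence or expression differs between the species. Sytl2, which tethers secretory vesicles, and Reep5, which shapes the endoplasmic reticulum, were far higher on the mouse side, as were the astrocyte genes Mlc1, Aqp4 and Aldoc. The imprinted genes Impact, Peg3 and Meg3 and the microglial receptor P2ry12 were also higher. Lower genes included Ccr8, a chemokine receptor, and Dusp7, a phosphatase that acts on kinases. A hamster transcript that binds a mouse probe poorly gives the same ratio as a gene that is expressed more in mouse.

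With limma on the 4 tissue arrays, 1659 genes were higher and 976 lower in mouse brain. With the dye orientation as a replicate block, which takes out the offset left by centring, 3480 were higher and 1736 lower. Leaving out either brain array left 0 calls by limma, with 5695 genes at an unadjusted p under 0.05 without replicate 1 and 5241 without replicate 2. Such a fit leaves the offset unbalanced. Each ± value of a tissue is limma's SE from the fit to all 4 arrays. It thus also draws on the spread of the other tissue. Phf20 averaged 7.75 ± 0.95 (n = 2), Pwp1 7.05 ± 1.13, Pcdhb17 6.98 ± 1.04 and Sytl2 6.26 ± 0.22. Sh3tc2 averaged 6.15 ± 0.96, AI593442 6.10 ± 0.21 and Reep5 6.07 ± 0.22. Miga1 averaged at least 7.70, Cav2 at least 6.71 and Hsbp1 at least 6.17, since values of these lay at the floor. Ccr8 averaged -6.37 ± 0.20, Dusp7 -6.00 ± 0.16 and 1700061I17Rik -5.78 ± 0.38. Foxa2 averaged -7.73 or below, C1qtnf6 -7.44 or below, Ccdc70 -7.44 or below, Krt27 -7.22 or below, Dpt -6.43 or below, Olfr616 -5.79 or below and Slfn4 -5.57 or below, each with a value at the floor. The adjusted p of these 20 genes lay between 0.0172 and 0.0484. With the arrays scaled, Pwp1 and Hsbp1 were not called.

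Of 17 astrocyte genes, 8 were higher and 0 lower by limma, and 11 and 0 when adjusted over the list alone, the same as at an unadjusted p under 0.05 (camera adjusted p = 0.0233; adjusted p = 0.992 with an estimated correlation). The replicate block raised this to 13 higher. Camera with an estimated correlation has only 2 residual degrees of freedom in the tissues, so its high p decides little here. Mlc1 averaged 5.11 ± 0.49, Aqp4 3.72 ± 0.27 and Aldoc 2.51 ± 0.18. S100b averaged 2.08 ± 0.12, but 1 of its features alone gave -1.46 and passed as lower (limma adjusted p = 0.0494). Among the features of Aldoc and S100b taken alone, 1 more was no longer called. Of 22 imprinted genes, 6 were higher and 2 lower, and 9 and 2 when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.384). Impact averaged 4.35 ± 0.20, Peg3 3.21 ± 0.35, Meg3 3.13 ± 0.22 and Sgce 2.25 ± 0.25. Of 19 microglia and macrophage genes, 3 were higher and 1 lower, and 4 and 2 when adjusted over the list alone (6 and 3 with the replicate block), with P2ry12 at 4.79 ± 0.18, Ctss at 3.04 ± 0.11 and Itgam at -1.27 ± 0.13. Of 38 neuron genes, 5 were higher and 1 lower, the same when adjusted over the list alone (6 and 3 with the replicate block), with Eno2 at 3.14 ± 0.39, Npy at 2.12 ± 0.17, Camk2a at 1.46 ± 0.21 and Grin2a at -3.50 ± 0.43. Neither of these 2 lists passed camera (each adjusted p = 0.952). Car2, an oligodendrocyte gene, averaged 5.37 ± 0.25. Of 17 oligodendrocyte genes, 6 were higher and 3 lower at an unadjusted p under 0.05 by limma. With the replicate block 4 were higher and 1 lower, and without it the list did not pass camera (adjusted p = 0.932).

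The fourth comparison set mouse liver against hamster liver. Higher on the mouse side were Cyp2f2, a cytochrome P450, Apoc1, a lipoprotein component, Kng1, a precursor of kinins, Mat1a, which makes the methyl donor of the cell, and Slco1a1, an uptake transporter. Idi1, Hmgcs1 and Sqle, which act in cholesterol synthesis, were higher too. Lower genes included Nnmt, which methylates nicotinamide, and Mgst2, a glutathione transferase.

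In mouse liver 388 genes were higher and 373 lower by limma, and 2697 and 1521 with the replicate block. Leaving out either liver array left 0 calls by limma, with 4869 genes at an unadjusted p under 0.05 without replicate 1 and 4949 without replicate 2. Apoc1 averaged 7.01 ± 0.37 (SE, n = 2). Values at the floor made the means of Ces3b at least 7.38, Kng1 at least 7.07, Cyp2f2 at least 7.04, Akr1c6 at least 6.90, Hamp at least 6.76, Cyp3a16 at least 6.64, Cyp2d34 at least 6.55, Fbln7 at least 6.48 and Fbp1 at least 6.40. Mybphl averaged -6.27 ± 0.58, Mgst2 -6.07 ± 0.35, Spns3 -5.96 ± 0.44, Olfr1230 -5.88 ± 0.63 and Hbb-y -5.86 ± 0.56. Means of 3110021A11Rik, Kdelr3, Cpne7, Cnga1 and Il1r2 lay between -5.59 and -5.41. Adjusted p of these 20 genes lay between 0.0222 and 0.0474. Scaling the arrays took Olfr1230 and Cpne7 below the threshold.

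Of 50 genes of cytochrome P450 and conjugation, 16 were higher and 4 lower, and 28 and 8 when adjusted over the list alone (camera adjusted p = 1.7e-04; adjusted p = 0.947 with an estimated correlation). The replicate block gave 29 higher and 6 lower. For this and the next lists, camera with an estimated correlation could hardly pass on 2 residual degrees of freedom. Ephx2 averaged 5.72 ± 0.23, Gstp1 4.85 ± 0.19 and Nnmt -3.09 ± 0.11. Of 23 bile acid genes, 7 were higher and 0 lower by limma, 9 and 1 when adjusted over the list alone, and 13 and 2 at an unadjusted p under 0.05 (camera adjusted p = 4.7e-04; adjusted p = 0.947 with an estimated correlation), with Acox2 at 4.12 ± 0.29, Slco1a1 at 3.89 ± 0.12, Nr1h4 at 3.57 ± 0.26 and Slc10a1 at 1.93 ± 0.11. Under the replicate block 14 were higher and 1 lower. Of 53 plasma protein genes, 13 were higher and 1 lower, and 22 and 5 when adjusted over the list alone (camera adjusted p = 8.3e-04; adjusted p = 0.947 with an estimated correlation), with F5 at 4.44 ± 0.11 and Fetub, the lower gene, at -2.71 ± 0.11. The counts became 25 and 5 with the replicate block. Of 19 cholesterol synthesis genes, 4 were higher and 0 lower by limma, 10 and 0 when adjusted over the list alone, and 13 and 0 at an unadjusted p under 0.05 (camera adjusted p = 7.8e-04; adjusted p = 0.947 with an estimated correlation). Under the replicate block 12 were higher. Idi1 averaged 2.28 ± 0.25, Hmgcs1 2.10 ± 0.17, Sqle 1.99 ± 0.20 and Cyp51 1.40 ± 0.11, and Hmgcs1 and Sqle were not called in a fit of the tissue and hybrid arrays together with a dye term. Of 30 genes of the urea cycle and amino acid catabolism, 6 were higher and 1 lower, and 9 and 3 when adjusted over the list alone (camera adjusted p = 0.0581). This list passed with the replicate block (14 higher, 3 lower, camera adjusted p = 0.0119; adjusted p = 0.937 with an estimated correlation), with Mat1a at 6.21 ± 0.12, Hpd at 4.61 ± 0.19, Fah at 4.26 ± 0.11 and Tat at 3.79 ± 0.11.

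Brain minus liver asked which species differences are particular to a tissue. A probe's preference for mouse sequence cancels there as far as it is multiplicative and the gene gives signal in both tissues. For a gene with signal in only 1 tissue the preference stays, and without intensities such genes cannot be told apart. Mat1a, for instance, had -0.40 in brain and 6.21 in liver, so its difference may repeat the liver ratio. The same limit holds for the lists of brain and liver genes. Sytl2 and Mlc1, the septin gene Septin5 and the kelch gene Klhl4 favoured mouse in brain over liver. Hamp, the hormone of iron balance, Uox, which breaks down urate, the complement gene C8b and the P450 gene Cyp2c40 favoured mouse in liver over brain.

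By limma 583 genes had a higher and 419 a lower mouse over hamster ratio in brain than in liver. With the replicate block the counts were 799 and 655, and with the arrays scaled 208 and 166. Leaving out any 1 of the 4 arrays left 0 calls by limma, with 4335 to 5010 genes at an unadjusted p under 0.05. Sytl2 differed by 6.50 ± 0.31, Mlc1 by 6.39 ± 0.69, Septin5 by 5.89 ± 0.35 and Klhl4 by 5.70 ± 0.61. Cyp2c40 differed by -8.16 or below, Hamp by -8.05 or below, Uox by -7.63 or below and C8b by -7.51 or below, each with a value at the floor. The adjusted p of the named genes here lay between 0.0324 and 0.0477. Scaling the arrays took Mlc1 and Cyp2c40 below the threshold. Of 17 astrocyte genes, 4 were higher and 0 lower by limma, 8 and 0 when adjusted over the list alone, and 9 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0164; adjusted p = 0.875 with an estimated correlation). Under the replicate block 7 were higher. Here too, the values with an estimated correlation rest on 2 residual degrees of freedom and decide little. Of 53 plasma protein genes, 2 were higher and 12 lower (3 and 21 when adjusted over the list alone), of 50 genes of cytochrome P450 and conjugation, 4 and 11 (7 and 28), and of 23 bile acid genes, 0 and 10 by limma (2 and 11, as at an unadjusted p under 0.05). Camera gave an adjusted p of 2.0e-05 for each of the last 3 lists (adjusted p = 0.875 with an estimated correlation). The block changed their counts to 2 and 22, 3 and 24, and 1 and 10. The urea cycle list had 1 higher and 7 lower (3 and 9 when adjusted over the list alone, camera adjusted p = 0.0163; adjusted p = 0.875 with an estimated correlation), and the cholesterol list had 0 and 3 by limma (0 and 5, and 0 and 8 at an unadjusted p under 0.05, camera adjusted p = 0.00325; adjusted p = 0.875 with an estimated correlation).

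**Figure D4:**
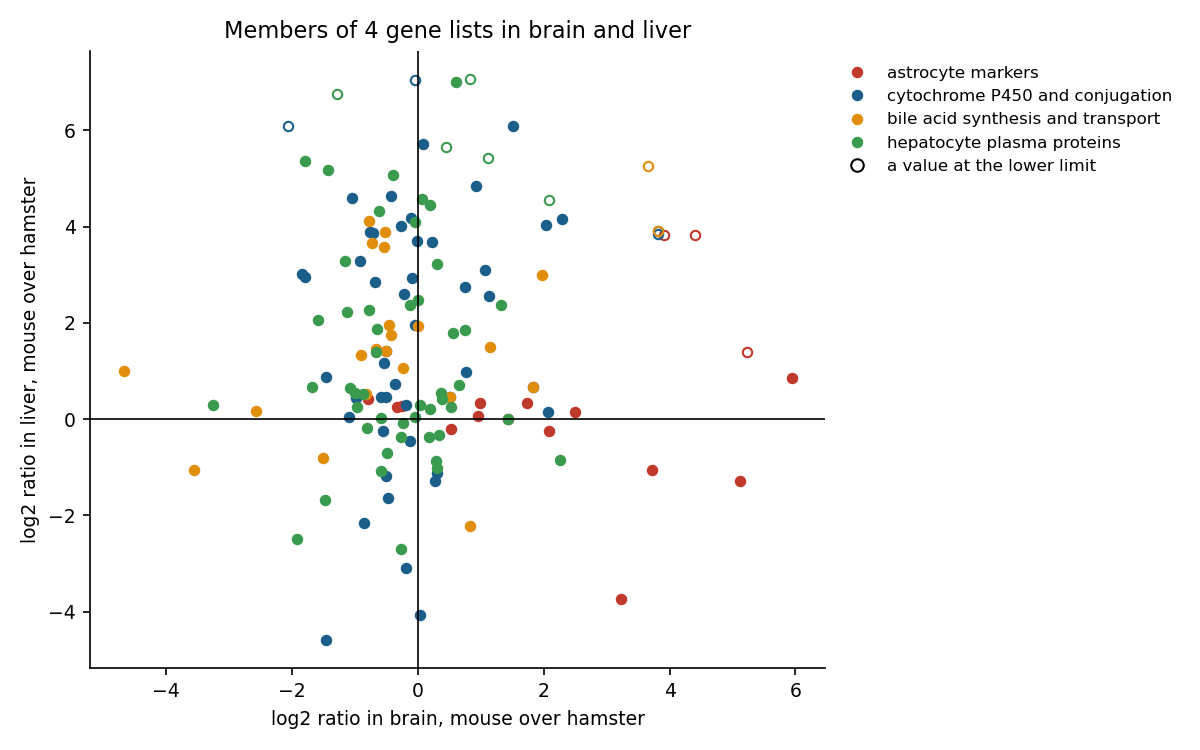
Mean log2 ratio, mouse over hamster, in brain (x axis) and liver (y axis) for members of 4 gene lists; open circles have a value at the lower limit. Of the 17 astrocyte genes 8 were called higher in brain, and of the 50 genes of cytochrome P450 and conjugation 16 in liver.

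The last comparison asked whether genes with a high mouse over hamster ratio in tissues were also raised in the hybrids. Across 16504 genes, which are not independent replicates, the mean ratio of both tissues correlated with the panel mean at Pearson's r = 0.317 (Spearman's rho = 0.232) and with the SD over lines at r = 0.249 (rho = 0.0809). Of the 1286 genes with a tissue ratio above 2 on the log2 scale, 58.3% were called higher in the panel. The share was 29.2% between 1 and 2, 14.6% between 0 and 1, 13.7% between -1 and 0 and 18.9% below -1. Brain and liver ratios correlated at r = 0.504 across genes.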

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

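The comparison of tissues was fixed before the data were examined, and the tests on unnamed features were chosen only after the result was seen.

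The mouse over hamster ratio differed between brain and liver by the test of the difference itself. By limma 583 genes were higher and 419 lower in brain minus liver. On the log2 scale Sytl2 differed by 6.50, Mlc1 by 6.39, Hivep1 by 6.15, Hspb3 by 6.04, Septin5 by 5.89, Arxes1 by 5.87, Klhl4 by 5.70, Zmat4 by 5.67, Aqp4 by 4.79 and S100b by 2.32. With the arrays scaled, Mlc1, Hivep1, Hspb3, Zmat4 and Aqp4 were no longer called. For S100b, 1 of its features alone gave -0.84. In the other direction Mat1a differed by -6.60, Akr1d1 by -5.66 and Slco1a1 by -4.41. Genes with a value at the floor are bounded: Cyp2c40 at -8.16 or below, Hamp at -8.05 or below, Krt27 at -7.68 or below, Uox at -7.63 or below, Olfr616 at -7.56 or below, C8b at -7.51 or below, Ccdc70 at -7.17 or below, Ces3b at -7.15 or below and Cyp2f2 at -7.09 or below. Of these, Cyp2c40, Krt27, Olfr616 and Ccdc70 were no longer called with the arrays scaled. A difference of tissues in the design is a biological explanation and was not tested apart from the tissues' probes.

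A signal also appeared in the 3066 features without a gene here, which only the alternatives by feature used. In the panel 170 of them were higher and 113 lower in both dye orientations alone. That is 5.54% higher, against 7.48% of the named genes. Feature 9588 averaged 3.84 on the log2 scale and feature 14989 averaged 3.38, and both were above 0 in 99 of 99 lines. No biological explanation was tested.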

How the results depend on the processing

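The fits without line 23, with its first array's sign turned, without wide arrays, with both dye orientations required, and with components removed before matching arrays were chosen only after the result was seen, as was giving the block beside tissue counts. Of 2646 values under alternatives, 1878 were the same, 277 kept direction but were no longer called, 485 moved and 6 reversed. For a tested value, the same meant that direction and call were kept. For a count or an untested correlation it meant staying within a set limit of the main value, and moved meant passing that limit. Counts inside the limit could still fall clearly. With exact zeros as missing, panel calls were 2161 higher and 1810 lower, against 3224 and 1887. Genes that differed between lines then numbered 1019 (7.31% of those tested), against 1466 (8.88%). These counts were taken as the same. Tk1 stayed called in each alternative that gave it a value. C1ra, Dtymk, S100a11 and Hspb8 had too many exact zeros to be tested with zeros as missing.

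Panel calls ranged from 3680 to 6087 higher and from 4087 to 4288 lower without 1 replicate. A median over lines gave 1978 higher, the matched lines alone 933 lower (71 of 99 lines left out), no size limit 5033 and 4462, and a limit of 0.5 gave 752 and 315. With replicate block and line as random block there were 3234 and 1885. The neighbours' median was 0.15 to 0.16 without 1 replicate, and the replicate 1 arrays alone did not pass (p = 0.0723). Without 1 replicate Sqle ranged from -2.14 to 0.39, Hmgcs1 from -2.46 to 0.85, Bub1 from -0.064 to 1.71 and Sparc from -0.71 to 2.12. The cause of these was not tested.

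Genes differing between lines numbered 767 with no replicate block and 3573 in the matched lines, whose choice by correlation favours calls; medians per line with no replicate block were 65 and 5. Distal chromosome 7 ranged from 0.0284 to 0.0468 without 1 replicate (adjusted p from 0.00133 to 0.0589 over alternatives). Lines matching their own second array rose from 28 to 64, 69 and 64 with 5, 10 and 20 components removed.

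With the replicate block, brain calls were 3480 and 1736, liver 2697 and 1521, and brain minus liver 799 and 655; the share higher in liver was 63.9%, against 51.0%. The block takes out the offset per feature, which widens the spread otherwise. Called in both tissues with the same sign were 4 genes in the design's fit and 1621 higher and 488 lower with the block, where independent lists give 569 and 160. Besides the urea cycle list, only oxidative phosphorylation in liver changed its camera call under the block (adjusted p 0.171 to 0.0119). Its estimated correlation was 0.778, and camera with that estimate gave an adjusted p of 0.937, on 1 residual degree of freedom. No named gene changed its call in the comparison it was named for. With tissue and hybrid arrays fitted together with a dye term, brain had 2916 higher, liver 2380 and 834, and the difference 887 and 953. With arrays scaled the difference had 208 and 166. Without 1 replicate limma called 0 genes in brain, liver and the difference, where the lone array is assumed to vary like the other tissue's; unadjusted p was under 0.05 for 4335 to 5695. The offset is then unbalanced. S100b reversed with 1 of its features alone (-1.46 in brain, -0.84 in the difference). Filters on missing values were not run, since none was missing. Signal over background is unknown.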

Other observations

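Tests of the neighbours in both orientations and against other position lists, of the highest genes by orientation, and both tests of the match of a line's arrays were chosen only after the result was seen. Tests of neighbours against Tk1, of probe preference and of random signs were fixed beforehand.

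Genes near Tk1 were higher in the hybrids. A dye effect that does not cancel is argued against as the whole cause, since 24.7% of the neighbours were higher in both orientations alone, against 7.40% of other genes (lower bound of the odds ratio 2.30). That bound treats the neighbours as independent, although they varied together across lines. The median alone does not settle this: in replicate 1 it was 0.164, inside the range of random lists (up to 0.179), and in replicate 2 it was 0.153 (up to 0.050). A rise of genes near any mouse fragment stays open. The highest median of the other 3 position lists was 0.0470, but the intervals of their medians reached up to 0.160, and that of the neighbours began at 0.0696 (95% bootstrap). Kept mouse DNA around Tk1 remains a candidate explanation: the median correlation across lines between Tk1 and its neighbours was 0.112, above the upper end of the 95% range of random lists (0.0665). The permutation p was 0.001, the smallest that 1000 draws can give (one-sided), Spearman's correlation gave a median of 0.104 (p = 0.001), and leaving out the 2 lines farthest from the median of Tk1 gave 0.0837 (p = 0.00400). Which fragments each line holds was not analysed here.

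The 12 highest panel means included Pigr and Tsga10, and also Tk1 and its listed neighbour Trim47. Whether more of the 12 lie near Tk1 was not examined, since gene positions were not analysed here. Preference of the probes for mouse RNA may explain part of the size of these means. The 12 genes had a median mouse over hamster ratio 1.04 above that of all genes on the log2 scale. The ratio ran from -1.15 to 3.07, so a high one is not shared by each of them. A dye effect is argued against, since the smallest mean of the 12 in either orientation was 1.14. Expression of the donor's copies is a biological explanation that was not tested. Lines hold random fragments, yet Pigr, Slc38a10, Tsga10, Hook1, Cst9 and 4930402H24Rik were above 0 in 99 of 99 lines. Their lowest line lay between 0.04 (Hook1) and 1.04 (Slc38a10). For these genes that argues against donor copies held by only part of the lines as the whole cause. For the other genes of the 12 it stays open.

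Few lines matched their own second array, with 28 of 99 ranked first. Structure shared by many genes is a candidate explanation, since removing 10 components raised this to 69. A search for exchanged labels between lines found partners for only a part of the unmatched lines. With 5, 10 and 20 components removed, 12 of 35, 5 of 30 and 7 of 35 unmatched lines had a mutual best partner in another line. At most 8.57% (3 of 35) had such a partner above the median correlation of matched lines. That limit would also leave out true exchanges of weaker correlation, so the search does not exclude exchanges. Single exchanges stay open: with 20 components removed, lines 14 and 6 were each other's best partners, at r = 0.451 and r = 0.183. With 5 and with 10 removed, no unmatched line formed such a pair. A wrong label with no partner was not excluded either. The first array of line 23 had a median r of -0.25 with the arrays of its orientation, below -0.3 with 35 of them. The panel counts without line 23 were 3296 higher and 1946 lower.

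The number of panel calls was not reached with random signs of the lines. Of 100 assignments of signs, only the real 1 gave as many calls as its 5111, and the highest of the others gave 2. Random signs also remove any offset that all lines share, such as one of the A23 RNA. The test therefore cannot exclude chance in A23 or another shared offset.

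Some process lists also varied together across lines. Mean correlation was 0.404 for ribosomal proteins, 0.371 for oxidative phosphorylation and 0.236 for chaperones. With the first 5 components removed these were 0.214, 0.0668 and 0.0437, and the position lists ran from 0.0370 to 0.0912. The difference between the kinds of list was not tested.

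Only 4 genes were called in both tissues with the same sign, against 39.0 higher and 22.1 lower for independent lists. The low number is no finding about the tissues, since the centring widens the spread between the arrays of a tissue. With the offset taken out by the replicate block, 1621 higher and 488 lower were shared, above the 569 and 160 of independent lists. Named after their values were seen, the 4 were Eea1 (1.68 in brain, 1.74 in liver), Gbf1 (1.19, 1.61), Uggt2 (1.88, 1.66) and Papss2 (-1.84, -1.92).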
